A study of Mus musculus with 6 samples.

How the data were processed

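The libraries were whole-transcriptome single-cell libraries made on the BD Rhapsody platform from ipsilateral hemispheres of Ms4a3-creERT2 Ai14 mice that received tamoxifen, per the labels' protocols. Per the same protocols, tissue was digested with papain and DNase I, strained, cleared of red blood cells and stained with Calcein-AM and Draq7, and libraries were sequenced on a DNBSEQ-T7. Groups and replicate numbers came from the sample titles. The deposited files hold whole-number UMI counts per gene and cell, not normalized, as the values show. Reads were processed with fastp 0.24.0 and STARsolo 2.7.11b against mm10, per the submitters' processing notes, and how the authors filtered barcodes before deposit is not given in the sources used here. All deposited barcodes had at least 500 UMIs. One library spells the reporter's symbol differently, and features were matched by identifier.

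From these counts, cells with at least 500 UMIs, at least 200 detected genes and at most 20% mitochondrial UMIs were kept. Of 16494, 17431, 16111, 17471, 15117 and 14778 barcodes (sham replicates 1 and 2, day 1 replicates 1 and 2, day 3 replicates 1 and 2), 15738, 16494, 15411, 17029, 14333 and 14053 remained. Scrublet, run per library in scanpy 1.11.5 with an expected rate of 6%, marked 5.34%, 4.88%, 3.50%, 4.92%, 2.96% and 2.31% of them as doublets, which were left out along with clusters of which over 50% was marked. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave Leiden clusters at resolution 1 (igraph 0.11.9, Python 3.11.15), without batch integration. Clusters were named from fixed marker lists by the mean standardized level of the markers, with a score of at least 0.4 and at least 3 detected markers. Clusters holding markers of several classes were split once (resolution 0.5) and stayed unnamed where that persisted, where the 10 leading genes held more listed markers of another class, or where depth was low and these held none of their own. These naming thresholds were set after the data were seen, with tdTomato per cluster in view though not used for naming, and the markers before.

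UMI counts were summed per library and class. The 6 classes chosen for gene tests, each with at least 30 cells in every library, were tested in edgeR 4.0.16 (R 4.3.3) with glmQLFit and glmQLFTest, TMM scaling, filterByExpr at its defaults, and all 3 groups in 1 fit, so that they shared the estimate of the spread. Adjusted p-values are Benjamini-Hochberg over all genes tested in a class and contrast, with a threshold of 0.05. Class cell counts per library were tested with the same edgeR test with the log of all kept cells as offset, adjusted over the classes. Lists fixed in advance were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists of that class and contrast, and lists of other classes' markers likewise. Tests are 2-sided. Shares of cells with a tdTomato UMI were also taken after thinning each cell to 2000 UMIs, leaving out shallower cells. Coordinates are those of GENCODE vM21 on mm10 (GRCm38), 1-based, and 99.5% of the 31254 gene identifiers matched it. Ratios carry 95% intervals that cover counting error only.

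The classes, contrasts, tests, lists, markers, the rule for named genes and the alternative settings were fixed before the data were examined. The rule takes, per class and contrast, the largest rises and falls among genes that passed, with a mean of at least 5 on the log2 CPM scale, no overlap of libraries, no predicted, ribosomal or mitochondrial gene name and no marker of another class, then the members of each list with the smallest p, then Ms4a3 and the reporter. For length, at most the first 2 of each part are given, in rule order, skipping markers of the class itself. Which lists are described in full was decided after the values were seen. Genes that share reads with near-identical copies (such as the MHC class I, Hspa1 and Ifit genes) are uncertain to the extent that the counting split them.

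The gene test was tested on simulated data drawn from the means and library sizes of day 1 against sham, with 200 genes changed per class. It recovered 73.4% in microglia, 16% in monocyte-macrophages, 21.6% in neutrophils, 70.4% in endothelial cells, 58.2% in astrocytes and 67.3% in oligodendrocytes of genes changed 2-fold, over 15165, 11046, 6122, 12689, 14228 and 13231 genes. For genes changed 4-fold it recovered 90.6%, 43.8%, 80.6%, 93.9%, 92.8% and 94.8% in the same order. It called 0 genes when nothing was changed, by edgeR with Benjamini-Hochberg adjustment. With changed genes present, 3 of 159, 3 of 60, 4 of 100, 11 of 173, 8 of 155 and 13 of 171 calls were false, in the same order. The share test recovered 20 of 20 simulated 4-fold changes and called 3 of 340 unchanged classes. Classes varying like day 1 monocyte-macrophages may be recovered less often. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 21.3, 141 and 75.5 in sham, day 1 and day 3), so none was counted as a duplicate.

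Alternative settings for genes were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, doublets kept, a stricter cell filter (1000 UMIs, 10% mitochondrial), Leiden resolution 2, the same number of cells from every library (2610 in microglia, 31 in monocyte-macrophages, 46 in neutrophils), other classes' markers left out, the replicate number as a block, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups. For shares, TMM factors over class counts took the place of the scaling alternatives, and for lists an estimated correlation and fry. After the data were seen, fits without cycling clusters and without genes at least 10 times more abundant in myeloid cells were added.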

Results

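Single-cell RNA sequencing was carried out on brain cells of Ms4a3-creERT2 Ai14 mice, in which tamoxifen switches on the red fluorescent protein tdTomato in cells that express Ms4a3, a gene of granulocyte-monocyte progenitors, and in their progeny. Transient middle cerebral artery occlusion (tMCAO), a stroke model in which a large artery of the brain is blocked and reopened, was compared with sham surgery in the hemisphere on the operated side, 1 day and 3 days later. The 3 groups (sham, tMCAO day 1, tMCAO day 3) had 2 libraries each. Per library, sham replicates held 68125690 and 71428127 unique molecular identifier (UMI) counts, day 1 replicates 84737624 and 86947495, and day 3 replicates 102594643 and 104315840. Median UMIs per cell were 3782 and 3773 in sham, 4769 and 4367 on day 1, and 6020 and 6290 on day 3. Nothing in the labels says that the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Group values are means ± SD (n = 2 libraries). Classes are named from marker genes and stand for cells resembling that class. Largest rises and falls are ranked by fitted fold change among genes that passed, had a mean of at least 5 on the log2 CPM scale, had libraries that did not overlap and were no class marker. Values after ± in parentheses beside genes, or with a p, are SE, and the values before them log2 fold changes. CPM are UMI counts scaled to the same total per library and class. A fold given as "at least" is set against a floor of 3 UMIs over the group. Such a gene can rank first on a far larger fitted value, while its counts show only the floor. An example is Cxcl1 in monocyte-macrophages on day 1, with a fitted log2 fold change of 14.3.

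The comparison of cell shares asked which cells entered or were lost from the hemisphere after the occlusion. Monocyte-macrophages, blood-derived phagocytes, made up 0.226% ± 0.0243 of cells in sham, 5.22% ± 5.43 on day 1 and 39.3% ± 1.79 on day 3. Neutrophils made up 0.471% ± 0.25, 3.71% ± 3.57 and 4.82% ± 3.92, and T and NK cells 0.312% ± 0.0118, 0.525% ± 0.232 and 1.19% ± 0.443. Microglia, the resident macrophages of the brain, made up 36.7% ± 0.225 in sham, 36.1% ± 0.0149 on day 1 and 19.3% ± 0.705 on day 3. On day 3 against sham, edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment called higher shares of monocyte-macrophages (7.43 ± 1.14, adjusted p = 0.00673), neutrophils (3.35 ± 1.14, adjusted p = 0.0450) and T/NK cells (1.93 ± 0.45, adjusted p = 0.0168), and a lower share of microglia (-0.93 ± 0.19, adjusted p = 0.0113). Against day 1, the day 3 share of microglia was lower (-0.90 ± 0.19, adjusted p = 0.0253), while monocyte-macrophages (2.91 ± 0.92, adjusted p = 0.0537), T/NK cells (1.18 ± 0.44, adjusted p = 0.0702) and neutrophils (0.38 ± 1.03, adjusted p = 0.774) did not pass with the same test and adjustment. On day 1 against sham, 0 of 18 classes passed with edgeR, the only tool run on shares, and 4 had an unadjusted p under 0.05. Day 1 log2 fold changes were 4.52 ± 1.00, adjusted p = 0.106 for monocyte-macrophages, 2.98 ± 1.12, adjusted p = 0.219 for neutrophils, 0.75 ± 0.45, adjusted p = 0.411 for T/NK cells and -0.03 ± 0.18, adjusted p = 0.947 for microglia, by edgeR with BH adjustment.

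Several of these calls changed when a library was left out or the scaling was changed, and all adjusted p are from edgeR with BH adjustment. The monocyte-macrophage share on day 1 passed when either day 1 library was left out (2.60, adjusted p = 0.00751 without day 1 replicate 1 and 5.32, adjusted p = 5.08e-04 without day 1 replicate 2), as did day 3 against day 1 (4.83, adjusted p = 0.00167 without day 1 replicate 1 and 2.12, adjusted p = 0.0127 without day 1 replicate 2). The neutrophil call on day 3 was lost in several settings (4.03, adjusted p = 0.0975 without sham replicate 1, 2.89, adjusted p = 0.169 without sham replicate 2, 2.12, adjusted p = 0.223 without day 3 replicate 1 and 4.01, adjusted p = 0.0665 without day 3 replicate 2) and with the stricter cell filter (3.05, adjusted p = 0.0669). Neutrophils on day 3 against day 1 turned lower in part of the settings (-0.37, adjusted p = 0.794 without day 1 replicate 2 and -0.86, adjusted p = 0.674 without day 3 replicate 1). Microglia on day 3 did not pass against sham (-0.92, adjusted p = 0.0757 without sham replicate 1 and -0.93, adjusted p = 0.0750 without sham replicate 2) or against day 1 (-0.90, adjusted p = 0.0789 without sham replicate 1, -0.90, adjusted p = 0.0789 without sham replicate 2, -0.86, adjusted p = 0.0761 without day 3 replicate 1 and -0.94, adjusted p = 0.0916 without day 3 replicate 2) in these settings. The T/NK cell call on day 3 was lost in others (1.89 without sham replicate 1, 1.97 without sham replicate 2 and 1.49 without day 3 replicate 2). Day 3 against day 1 passed in 1 such fit, which also kept 1 day 1 library (1.72 without day 1 replicate 1). Shares sum to 100%, and with TMM factors over class counts the microglia values became -0.01, adjusted p = 0.941 on day 3 against sham and 0.03, adjusted p = 0.869 against day 1. With those factors T/NK cells (2.10, adjusted p = 0.0244) and monocyte-macrophages (3.82, adjusted p = 0.0342) passed on day 3 against day 1, and at Leiden resolution 2 microglia did not (-0.43, adjusted p = 0.211). Sub-clusters that stayed unnamed held 2.55% ± 0.0509 of cells in sham, 4.13% ± 0.265 on day 1 and 6.74% ± 1.09 on day 3.

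**Figure D1:**
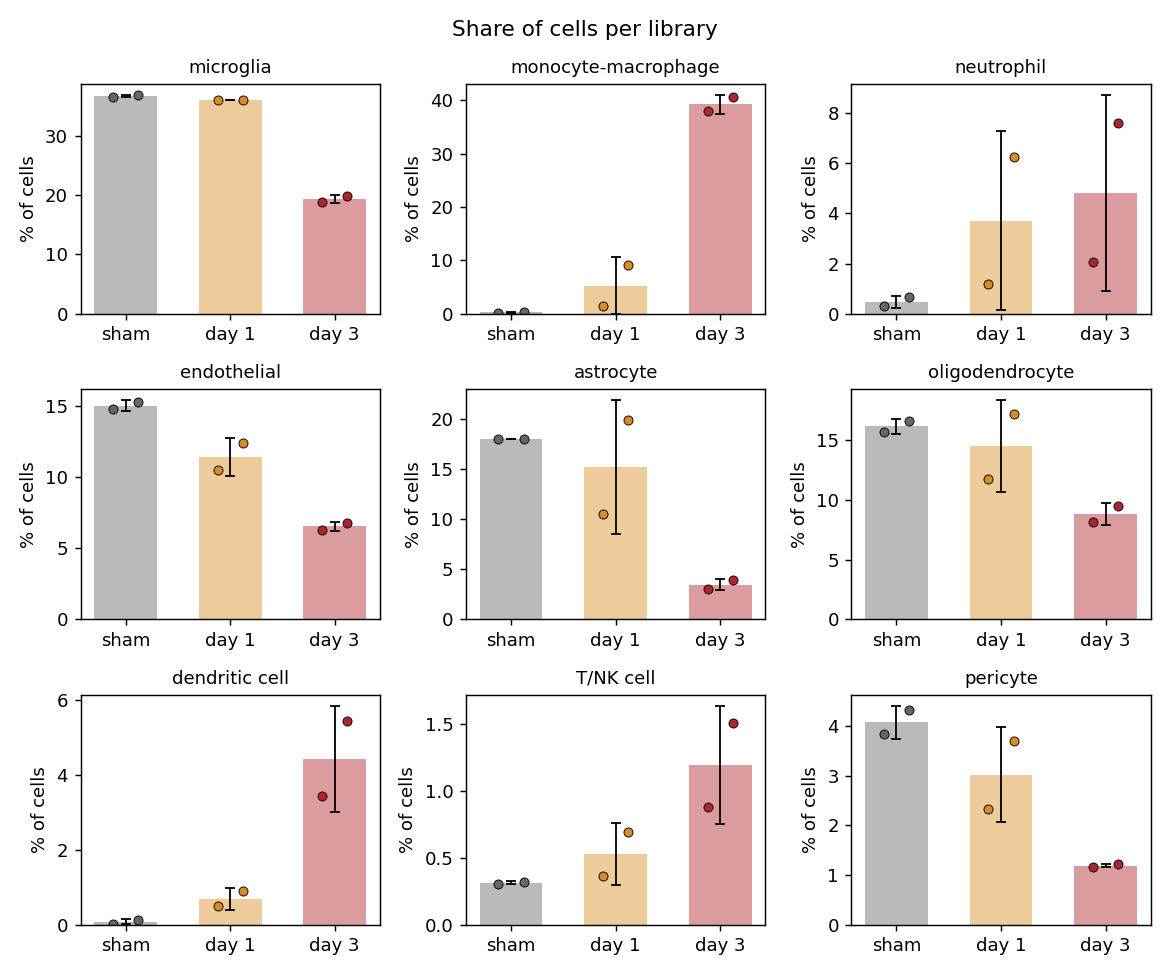
Share of cells per library for 9 classes, as percent of all kept cells, in sham, tMCAO day 1 and tMCAO day 3. Bars are means, error bars SD (n = 2) and points single libraries. The day 1 points of monocyte-macrophages lie at 9.06% and 1.38%.

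The reporter marks cells of the Ms4a3 lineage. tdTomato reached 261 ± 24.9 CPM in monocyte-macrophages of sham, 229 ± 19.3 on day 1 and 223 ± 46.5 on day 3, and 366 ± 130.3, 364 ± 4.07 and 345 ± 68.1 in neutrophils. Microglia, which arise outside this lineage, held 11.9 ± 0.108, 10.1 ± 0.0601 and 9.84 ± 1.22 and serve as background. These plain values show no fall in microglia. With TMM factors, the day 3 log2 fold change against sham ran from -0.093 to 0.209 with a library left out. B cells held 0 tdTomato UMIs in 68 cells of sham, 4 and 1 in the day 1 replicates and 0 and 2 in those of day 3. At least 1 tdTomato UMI was found in 56.7%, 63.6% and 70.0% of monocyte-macrophages, 63.0%, 49.7% and 40.0% of neutrophils and 4.58%, 5.64% and 8.43% of microglia (sham, day 1, day 3). Median depths behind these shares were 3752, 5856 and 7781, 3181, 2069 and 1609.5 and 3997, 5781 and 8661 UMIs per cell. Thinned to 2000 UMIs per cell, without shallower cells (12 of 69, 67 of 1562 and 162 of 10826, 26 of 142, 522 of 1114 and 1073 of 1333 and 637 of 11168, 422 of 11133 and 316 of 5321), the shares were 38.1%, 34.9% and 33.9%, 46.8%, 49.2% and 42.6% and 2.31%, 1.97% and 2.03%. Of the classes tested for genes, tdTomato rose in oligodendrocytes, from 3.17 ± 0.398 CPM in sham to 16.5 ± 4.24 on day 1 (2.26 ± 0.24, adjusted p = 2.55e-04) and 14.9 ± 0.95 on day 3 (2.13 ± 0.25, adjusted p = 2.97e-04), by edgeR with BH adjustment. In endothelial cells it was 50.8 ± 5.16 in sham, 42.7 ± 3.78 on day 1 and 84.8 ± 18.4 on day 3, passing on day 3 against sham (0.96 ± 0.15, adjusted p = 0.00193) and against day 1 (1.17 ± 0.16, adjusted p = 0.00119) with the same edgeR test and adjustment. In astrocytes it rose on day 1 (0.70 ± 0.17, adjusted p = 0.0309) and day 3 (1.08 ± 0.19, adjusted p = 0.00522), also by edgeR with BH adjustment. On day 1, it did not pass without sham replicate 1, sham replicate 2 or day 1 replicate 2, nor on day 3 without sham replicate 1. The remaining contrasts of these classes, and all contrasts in microglia, monocyte-macrophages and neutrophils, did not pass. Ms4a3 itself (ENSMUSG00000024681, chromosome 19, 11629496 to 11640851 of mm10) gave 9 UMIs in sham neutrophils and 1 in sham T/NK cells, and was listed at 0 in the other named classes.

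**Figure D2:**
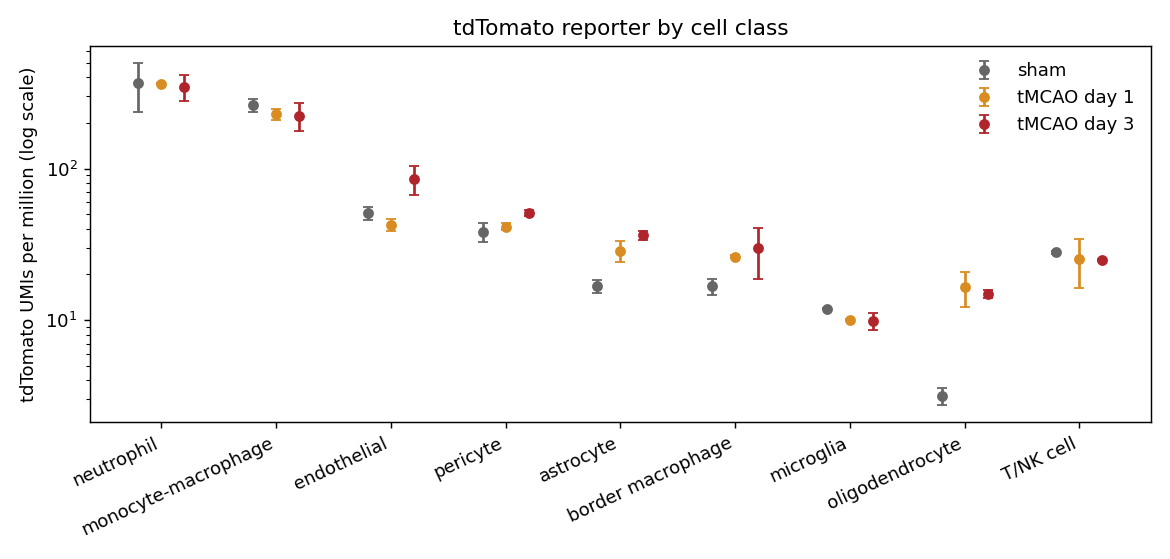
tdTomato in plain CPM (without TMM factors) of each class (log scale) in sham, tMCAO day 1 and tMCAO day 3. Points are means of 2 libraries and bars SD; neutrophils and monocyte-macrophages lie above every other class drawn.

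On day 1, microglia held fewer transcripts of most homeostatic genes than in sham, and more of most disease-associated, interferon response and inflammatory genes. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) rose from 4.33 ± 2.21 to 3169.8 ± 1.63 CPM. Sham microglia lay mostly in clusters 0 (49.5%) and 5 (39.4%), and those of day 1 in clusters 33 (36.7%) and 1 (30.0%). Markers that named the class make up 12 of the 20 homeostatic genes and are not used as examples. The largest rises were those of Spp1, osteopontin, a secreted phosphoprotein (log2 fold change 9.53 ± 0.35, adjusted p = 2.13e-05) and Il1rn, the interleukin 1 receptor antagonist (9.05 ± 0.30, adjusted p = 1.40e-05), and the largest falls those of Ube2c, a mitotic ubiquitin-conjugating enzyme (-4.37 ± 1.07, adjusted p = 0.0150) and Hmmr, a spindle-associated hyaluronan receptor (-4.11 ± 1.15, adjusted p = 0.0246), by edgeR with BH adjustment. Of 20 homeostatic microglia genes, 17 fell and 3 did not pass (18 fell adjusted over the list alone, camera adjusted p = 1.43e-22). Among them were Entpd1, the ectonucleotidase CD39 (-1.54 ± 0.08) and Slc2a5, a fructose transporter (-1.94 ± 0.10). In the disease-associated microglia list, 15 rose, 1 fell and 5 did not pass of 21 measured genes (the same adjusted over the list alone, camera adjusted p = 1.38e-23). It included Ch25h, cholesterol 25-hydroxylase (5.71 ± 0.12) and Spp1 (9.53 ± 0.35). Interferon response genes numbered 22, of which 20 rose and 2 did not pass (21 rose adjusted over the list alone, camera adjusted p = 3.71e-19, adjusted p = 0.132 with an estimated correlation). Examples were Cxcl10, an interferon-induced chemokine (2.23 ± 0.09) and Isg15, an interferon-induced ubiquitin-like protein (2.73 ± 0.14). Of 21 inflammatory cytokine and chemokine genes, 17 rose, 2 fell and 2 did not pass (18 rose and 2 fell adjusted over the list alone, camera adjusted p = 9.69e-29). Among them were Ptgs2, cyclooxygenase 2 (3.77 ± 0.10) and Il1rn (9.05 ± 0.30). In the same cells, 10 rose and 8 did not pass of 18 monocyte-macrophage markers, 8 fell and 6 did not pass of 14 endothelial markers, 8 fell and 4 did not pass of 12 oligodendrocyte markers, 1 rose, 5 fell and 8 did not pass of 14 astrocyte markers, 5 fell and 1 did not pass of 6 choroid plexus markers and 5 fell of 5 B cell markers by edgeR. edgeR called 6930 of 15165 genes on day 1 against sham, 3662 higher and 3268 lower, against 4595 without sham replicate 1. Ube2c did not pass when either day 1 replicate was left out. Hmmr did not pass without sham replicate 2 (log2 fold change -0.998), day 1 replicate 1 or day 1 replicate 2 (log2 fold change -4.86). A kept call had a log2 fold change of -1.79 (Ube2c, without sham replicate 2).

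On day 3, homeostatic genes were mostly lower than in sham and disease-associated, interferon response and cell cycle genes mostly higher. Cd5l rose from 0.118 ± 0.0628 to 204 ± 61.9 CPM. Clusters 32 (28.0%) and 1 (17.4%) held the largest parts of day 3 microglia. Ranked by fold change, Spp1 (log2 fold change 11.54 ± 0.37, adjusted p = 1.00e-05) and Cd5l, a secreted scavenger receptor-family protein of macrophages (10.73 ± 0.43, adjusted p = 1.23e-05) rose most and Lsamp, a neural adhesion molecule (-5.05 ± 0.52, adjusted p = 2.49e-04) and Hspa1b, an inducible HSP70 (-3.93 ± 0.54, adjusted p = 8.50e-04) fell most by edgeR with BH adjustment. In the homeostatic microglia list, 2 rose, 15 fell and 3 did not pass of 20 measured genes (the same adjusted over the list alone, camera adjusted p = 9.90e-11). It included Entpd1 (-1.62 ± 0.08) and Crybb1, a crystallin (-2.38 ± 0.13). Disease-associated microglia genes numbered 21, of which 21 rose (the same adjusted over the list alone, camera adjusted p = 2.12e-38). Examples were Ch25h (6.65 ± 0.13) and Fabp5, a fatty acid-binding protein (7.33 ± 0.18). Of 22 interferon response genes, 22 rose (the same adjusted over the list alone, camera adjusted p = 4.42e-15, adjusted p = 0.155 with an estimated correlation). Among them were Cxcl10 (2.16 ± 0.09) and Ifitm3, an interferon-induced membrane protein (3.50 ± 0.20). In the cell cycle list, 22 rose and 3 did not pass of 25 measured genes (24 rose adjusted over the list alone, camera adjusted p = 2.45e-05, adjusted p = 0.388 with an estimated correlation). It included Mcm6, a subunit of the replicative helicase (2.75 ± 0.21) and Pcna, the DNA polymerase clamp (1.51 ± 0.15). For markers of other classes, 13 rose and 5 did not pass of 18 monocyte-macrophage markers, 1 rose, 12 fell and 1 did not pass of 14 astrocyte markers, 3 rose, 9 fell and 2 did not pass of 14 endothelial markers and 8 fell and 4 did not pass of 12 oligodendrocyte markers by edgeR. In all, 9087 of 15165 genes passed with edgeR, 4751 higher and 4336 lower.

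Between day 1 and day 3, nearly all cell cycle genes rose in microglia and most inflammatory genes fell. Ube2c rose from 0.656 ± 0.269 to 128 ± 12.3 CPM. Among genes that rose, Ube2c (log2 fold change 7.59 ± 1.07, adjusted p = 0.00181) and Birc5, survivin, a mitotic protein (6.54 ± 0.99, adjusted p = 0.00232) led, and among genes that fell, Hspa1b (-4.31 ± 0.54, adjusted p = 0.00117) and Il1rn (-4.22 ± 0.21, adjusted p = 1.34e-04) (edgeR, BH adjustment). Inflammatory cytokine and chemokine genes numbered 21, of which 2 rose, 15 fell and 4 did not pass (the same adjusted over the list alone, camera adjusted p = 2.79e-08, adjusted p = 0.0848 with an estimated correlation). Examples were Ptgs2 (-2.01 ± 0.10) and Il1rn (-4.22 ± 0.21). Of 25 cell cycle genes, 24 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 4.04e-08, adjusted p = 0.424 with an estimated correlation). Among them were Ccnb2, a mitotic cyclin (5.63 ± 0.76) and Ube2c (7.59 ± 1.07). Of other-class markers measured here, 10 rose and 8 did not pass of 18 monocyte-macrophage markers and 11 fell and 3 did not pass of 14 astrocyte markers by edgeR. By edgeR, 3638 of 15165 genes were higher and 2955 lower, 6593 together, against 4270 without day 3 replicate 2.

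In monocyte-macrophages, several inflammatory, interferon response and glycolysis genes were higher on day 1 than in sham. Ccl7 rose from 5.61 ± 7.94 to 409 ± 14.0 CPM. The class was rare in sham, at 69 cells with 164629 and 132979 UMIs per library, which limits every comparison with sham. Sham cells lay mainly in clusters 24.0 (44.9%) and 25 (33.3%) and day 1 cells in cluster 25 (84.8%). Adgre4 and Ace were among the leading genes of 24.0 (3.65% of day 1 cells). Whether its share explains their falls below was not tested. The largest rises were those of Cxcl1, a neutrophil chemoattractant (at least 17.3-fold higher, adjusted p = 0.0194) and Myo1e, a class I myosin (at least 13.9-fold higher, adjusted p = 0.00590), and the largest falls those of Ace, angiotensin-converting enzyme (log2 fold change -3.04 ± 0.59, adjusted p = 0.0230) and Pou2f2, a lymphoid and myeloid transcription factor (-2.29 ± 0.41, adjusted p = 0.0171), by edgeR with BH adjustment. In the inflammatory cytokine and chemokine list, 10 rose and 11 did not pass of 21 measured genes (17 rose adjusted over the list alone, camera adjusted p = 7.40e-36, adjusted p = 0.118 with an estimated correlation). It included Ccl7, a monocyte chemoattractant (68.4-fold, counting interval 18.9 to 565) and Il1a, interleukin 1 alpha (3.40 ± 0.36). Interferon response genes numbered 22, of which 10 rose and 12 did not pass (15 rose adjusted over the list alone, camera adjusted p = 2.02e-17, adjusted p = 0.140 with an estimated correlation). Examples were Rsad2, viperin, an antiviral protein (4.10 ± 0.41) and Isg15 (21.4-fold, counting interval 7.31 to 104). Of 21 glycolysis and hypoxia genes, 6 rose and 15 did not pass (14 rose adjusted over the list alone, camera adjusted p = 9.97e-12, adjusted p = 0.229 with an estimated correlation). Among them were Vegfa, vascular endothelial growth factor A (2.88 ± 0.45) and Pgam1, a glycolytic enzyme (1.33 ± 0.26). In the same cells, 1 rose, 1 fell and 10 did not pass of 12 neutrophil markers by edgeR. Of the genes called, 75.5% were higher by edgeR, 65.8% of 272 by edgeR with DESeq2 size factors and 46.3% of 711 by DESeq2's Wald test. edgeR called 314 of 11046 genes on day 1 against sham, 237 higher and 77 lower, against 37 without sham replicate 2, 32 without day 1 replicate 1, 578 without day 1 replicate 2, 1258 with Leiden resolution 2, 0 by edgeR with no filter on low counts (1977 at an unadjusted p under 0.05) and 711 by the DESeq2 Wald test. Cxcl1 did not pass without sham replicate 1. Without sham replicate 2, Cxcl1, Myo1e, Ace (log2 fold change -1.71), Pou2f2 (log2 fold change -1.46), Vegfa and Pgam1 did not pass. Without day 1 replicate 1, Cxcl1, Ace (log2 fold change -2.26), Pou2f2 and Pgam1 did not pass.

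On day 3, most macrophage maturation genes were higher in monocyte-macrophages than in sham and most classical monocyte genes lower. Cd63 rose from 87.1 ± 19.8 to 2227 ± 116 CPM. Clusters 25 (39.4%) and 26.5 (15.6%) held the largest parts of the day 3 cells. Markers that named the class make up 11 of the 18 classical monocyte genes and 3 of the 22 maturation genes. Ranked by fold change, Cxcl1 (at least 17.6-fold higher, adjusted p = 0.00537) and Myo1e (at least 16.4-fold higher, adjusted p = 8.59e-04) rose most and Adgre4, an adhesion G protein-coupled receptor (log2 fold change -6.54 ± 0.66, adjusted p = 2.17e-04) and Ace (-5.96 ± 0.61, adjusted p = 2.34e-04) fell most by edgeR with BH adjustment. In the macrophage maturation list, 14 rose and 8 did not pass of 22 measured genes (16 rose adjusted over the list alone, camera adjusted p = 2.22e-26, adjusted p = 0.0547 with an estimated correlation). It included Cd63, a lysosomal tetraspanin (4.66 ± 0.27) and Ctsl, a lysosomal protease (2.54 ± 0.28). Classical monocyte genes numbered 18, of which 1 rose, 10 fell and 7 did not pass (2 rose and 14 fell adjusted over the list alone, camera adjusted p = 1.62e-14, adjusted p = 0.100 with an estimated correlation). Of 21 inflammatory cytokine and chemokine genes, 6 rose, 1 fell and 14 did not pass (9 rose and 2 fell adjusted over the list alone, camera adjusted p = 3.34e-04, adjusted p = 0.450 with an estimated correlation). Among them were Ccl7 (53.4-fold, counting interval 14.8 to 441) and Cxcl16, a transmembrane chemokine (2.60 ± 0.33). For markers of other classes, 3 fell and 9 did not pass of 12 neutrophil markers and 1 rose, 5 fell and 8 did not pass of 14 endothelial markers by edgeR. Of the genes called, 55.9% were higher by edgeR, 49.7% of 1048 by edgeR with DESeq2 size factors and 36.2% of 1547 by DESeq2's Wald test. In all, 1085 of 11046 genes passed with edgeR, 606 higher and 479 lower, against 423 without sham replicate 2, 612 with the same number of cells, 1739 with Leiden resolution 2 and 281 with no filter on low counts. Cxcl1 did not pass without sham replicate 2.

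From day 1 to day 3, most inflammatory genes fell in monocyte-macrophages while most macrophage maturation and cell cycle genes rose. Apoe rose from 881 ± 29.6 to 6069 ± 509.9 CPM. Among genes that rose, Htr2b, a serotonin receptor (log2 fold change 4.20 ± 0.27, adjusted p = 4.94e-06) and Fabp4, a fatty acid-binding protein (4.05 ± 0.35, adjusted p = 2.04e-05) led, and among genes that fell, Ccl24, eotaxin-2 (-7.53 ± 0.43, adjusted p = 2.00e-06) and Inhba, the activin A subunit (-6.09 ± 0.57, adjusted p = 3.17e-05) (edgeR, BH adjustment). In the macrophage maturation list, 14 rose, 1 fell and 7 did not pass of 22 measured genes (16 rose and 2 fell adjusted over the list alone, camera adjusted p = 3.21e-11, adjusted p = 0.334 with an estimated correlation). It included Cd63 (2.21 ± 0.20) and Apoe, apolipoprotein E (2.78 ± 0.25). Inflammatory cytokine and chemokine genes numbered 21, of which 1 rose, 13 fell and 7 did not pass (1 rose and 15 fell adjusted over the list alone, camera adjusted p = 4.27e-08, adjusted p = 0.334 with an estimated correlation). Examples were Il6, interleukin 6 (-5.14 ± 0.28) and Il1rn (-4.05 ± 0.32). Of 25 cell cycle genes, 17 rose and 8 did not pass (19 rose adjusted over the list alone, camera adjusted p = 3.21e-11, adjusted p = 0.334 with an estimated correlation). Among them were Ccna2, cyclin A2 (38.8-fold, counting interval 13.3 to 189) and Birc5 (4.13 ± 0.47). Of other-class markers measured here, 1 rose, 9 fell and 2 did not pass of 12 neutrophil markers and 9 fell and 4 did not pass of 13 astrocyte markers by edgeR. By edgeR, 1125 of 11046 genes were higher and 1087 lower, 2212 together, against 1134 without day 1 replicate 1, 987 without day 3 replicate 1, 727 without day 3 replicate 2, 207 with the same number of cells, 1141 with Leiden resolution 2 and 1089 with no filter on low counts.

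Day 1 neutrophils held more transcripts of most inflammatory and interferon response genes than sham neutrophils, and fewer of most granule genes. Chil3 fell from 3447 ± 1179 to 411 ± 92.8 CPM. All neutrophils of every group lay in cluster 23, and sham held 96 and 46 per library, which limits comparisons with sham. Of the neutrophils, only those of sham held Ms4a3 UMIs (9). Whether immature sham cells explain falls against sham was not tested. Markers that named the class make up 10 of the 17 granule genes. The largest rises were those of Msr1, a scavenger receptor (at least 26.5-fold higher, adjusted p = 3.98e-04) and Gdf15, a stress-induced TGF-beta family member (at least 13.9-fold higher, adjusted p = 0.00513), and the largest falls those of Pclaf, a PCNA-binding replication factor (log2 fold change -6.16 ± 0.74, adjusted p = 8.17e-05) and Top2a, DNA topoisomerase II alpha (-5.23 ± 0.55, adjusted p = 4.66e-05), by edgeR with BH adjustment. In the inflammatory cytokine and chemokine list, 16 rose and 2 did not pass of 18 measured genes (17 rose adjusted over the list alone, camera adjusted p = 4.20e-25, adjusted p = 0.101 with an estimated correlation). It included Ccl4, a chemokine (3.88 ± 0.41) and Il1a (4.96 ± 0.54). Interferon response genes numbered 20, of which 17 rose and 3 did not pass (18 rose adjusted over the list alone, camera adjusted p = 6.54e-18, adjusted p = 0.101 with an estimated correlation). Examples were Isg15 (3.94 ± 0.38) and Cxcl10 (4.10 ± 0.41). Of 17 neutrophil granule genes, 11 fell and 6 did not pass (15 fell adjusted over the list alone, camera adjusted p = 1.29e-14, adjusted p = 0.114 with an estimated correlation). Among them were Chil3, a chitinase-like protein (-3.08 ± 0.37) and Anxa1, annexin A1 (-2.49 ± 0.38). In the same cells, 6 fell and 3 did not pass of 9 astrocyte markers and 8 fell and 3 did not pass of 11 endothelial markers by edgeR. edgeR called 1266 of 6122 genes on day 1 against sham, 761 higher and 505 lower, against 375 without sham replicate 1, 774 without day 1 replicate 1 and 513 with the same number of cells. Gdf15 and Pclaf (log2 fold change -4.39) did not pass without sham replicate 1.

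On day 3, most tissue neutrophil and inflammatory genes were higher than in sham neutrophils and nearly all granule genes lower. Siglecf rose from 8.84 ± 2.06 to 172 ± 31.7 CPM. Ranked by fold change, Gpc3, a glypican (at least 28.3-fold higher, adjusted p = 1.29e-04) and Cxcl1 (at least 21.9-fold higher, adjusted p = 0.00124) rose most and Pclaf (log2 fold change -6.64 ± 0.74, adjusted p = 1.29e-04) and Fcnb, ficolin B (-6.43 ± 0.74, adjusted p = 1.31e-04) fell most by edgeR with BH adjustment. In the inflammatory cytokine and chemokine list, 11 rose, 1 fell and 6 did not pass of 18 measured genes (15 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.06e-11, adjusted p = 0.187 with an estimated correlation). It included Ccl2, a monocyte chemoattractant (58.1-fold, counting interval 10.3 to 2302) and Tnf, tumour necrosis factor (2.74 ± 0.38). Tissue neutrophil genes numbered 18, of which 13 rose, 1 fell and 4 did not pass (15 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.95e-13, adjusted p = 0.187 with an estimated correlation). Examples were Siglecf, a sialic acid-binding lectin (4.14 ± 0.50) and Spp1 (4.63 ± 0.59). Of 17 neutrophil granule genes, 16 fell and 1 did not pass (17 fell adjusted over the list alone, camera adjusted p = 7.74e-26, adjusted p = 0.187 with an estimated correlation). Among them were Cybb, the catalytic subunit of NADPH oxidase (-3.60 ± 0.42) and Chil3 (-2.92 ± 0.36). For markers of other classes, 9 fell of 9 astrocyte markers and 7 fell and 4 did not pass of 11 endothelial markers by edgeR. In all, 1019 of 6122 genes passed with edgeR, 467 higher and 552 lower, against 267 without sham replicate 1, 501 without day 3 replicate 1 and 312 with the same number of cells. Cxcl1 did not pass without sham replicate 1. A kept call had a log2 fold change of 11.29 (Spp1, without sham replicate 1).

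Most interferon response genes were lower in neutrophils on day 3 than on day 1. Cxcl10 fell from 947 ± 255 to 68.2 ± 26.6 CPM. Among genes that rose, Gpc3 (log2 fold change 5.14 ± 0.42, adjusted p = 1.52e-05) and Siglecf (2.91 ± 0.34, adjusted p = 1.72e-04) led, and among genes that fell, Lpl, lipoprotein lipase (-4.32 ± 0.43, adjusted p = 5.08e-05) and Rsad2 (-3.83 ± 0.42, adjusted p = 1.31e-04) (edgeR, BH adjustment). In the interferon response list, 16 fell and 4 did not pass of 20 measured genes (19 fell adjusted over the list alone, camera adjusted p = 4.54e-33, adjusted p = 0.0914 with an estimated correlation). It included Cxcl10 (-3.72 ± 0.35) and Isg15 (-2.90 ± 0.29). Inflammatory cytokine and chemokine genes numbered 18, of which 1 rose, 8 fell and 9 did not pass (2 rose and 8 fell adjusted over the list alone, camera adjusted p = 6.56e-10, adjusted p = 0.146 with an estimated correlation). Examples were Ccl12, a monocyte chemoattractant (-3.02 ± 0.36) and Osm, oncostatin M (-2.31 ± 0.28). Of other-class markers measured here, 1 fell and 8 did not pass of 9 astrocyte markers by edgeR. By edgeR, 63 of 6122 genes were higher and 290 lower, 353 together, against 185 without day 3 replicate 1 and 49 with the same number of cells.

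Endothelial cells, which line the vessels, held fewer transcripts of most blood-brain barrier genes on day 1 than in sham, and more of most angiogenesis genes. Adamts4 (ENSMUSG00000006403, chromosome 1, 171250421 to 171260637) rose from 5.17 ± 1.49 to 301 ± 4.02 CPM. Sham cells lay in cluster 9 (94.2%) and day 1 cells mainly in cluster 10 (54.1%). Markers that named the class make up 5 of the 19 barrier genes. The largest rises were those of Adamts4, an aggrecanase (log2 fold change 5.86 ± 0.16, adjusted p = 4.06e-07) and Inhbb, an activin subunit (5.30 ± 0.38, adjusted p = 1.22e-04), and the largest falls those of Trpm3, a cation channel (-1.62 ± 0.32, adjusted p = 0.00970) and Trp53inp1 (-1.51 ± 0.13, adjusted p = 2.30e-04), by edgeR with BH adjustment. Of 19 blood-brain barrier genes, 1 rose, 16 fell and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 2.25e-11, adjusted p = 0.0638 with an estimated correlation). Among them was Itih5 (-1.30 ± 0.14). In the angiogenesis list, 11 rose and 8 did not pass of 19 measured genes (15 rose adjusted over the list alone, camera adjusted p = 8.68e-17). It included Mcam, the adhesion molecule CD146 (2.91 ± 0.14) and Col4a1, a basement membrane collagen chain (1.73 ± 0.13). In the same cells, 6 rose and 9 did not pass of 15 monocyte-macrophage markers and 9 fell and 3 did not pass of 12 microglia markers by edgeR. edgeR called 2208 of 12689 genes on day 1 against sham, 1305 higher and 903 lower, against 915 without sham replicate 1, 1259 without sham replicate 2, 1255 without day 1 replicate 1 and 1441 with the same number of cells.

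On day 3, most cell cycle and angiogenesis genes were higher in endothelial cells than in sham and most barrier genes lower. Lamb1 (ENSMUSG00000002900, chromosome 12, 31265234 to 31329644) rose from 1.39 ± 0.19 to 67.7 ± 10.6 CPM. Most day 3 cells lay in cluster 10 (65.0%). Among the largest rises was that of Spp1 (log2 fold change 6.22 ± 0.45, adjusted p = 4.07e-05), and among the largest falls were those of Gpc5, a glypican (-4.87 ± 0.74, adjusted p = 0.00143) and Lsamp (-4.32 ± 0.53, adjusted p = 4.34e-04), by edgeR with BH adjustment. Blood-brain barrier genes numbered 19, of which 3 rose, 12 fell and 4 did not pass (3 rose and 13 fell adjusted over the list alone, camera adjusted p = 3.89e-06, adjusted p = 0.141 with an estimated correlation). Examples were Mfsd2a, a lysophospholipid transporter of the barrier (-1.70 ± 0.12) and Itih5 (-1.35 ± 0.14). Of 19 angiogenesis genes, 12 rose, 2 fell and 5 did not pass (14 rose and 2 fell adjusted over the list alone, camera adjusted p = 1.88e-13, adjusted p = 0.0599 with an estimated correlation). Among them were Lamb1, a laminin chain (5.58 ± 0.21) and Mcam (2.68 ± 0.14). In the cell cycle list, 21 rose and 4 did not pass of 25 measured genes (22 rose adjusted over the list alone, camera adjusted p = 1.36e-30, adjusted p = 0.0675 with an estimated correlation). It included Mki67, the proliferation marker Ki-67 (5.13 ± 0.27) and Ccnb2 (6.38 ± 0.38). Gpc5 and Lsamp also led astrocyte cluster 14. For markers of other classes, 14 rose and 1 did not pass of 15 monocyte-macrophage markers, 9 fell and 3 did not pass of 12 microglia markers and 1 rose, 7 fell and 6 did not pass of 14 astrocyte markers by edgeR. In all, 3833 of 12689 genes passed with edgeR, 2165 higher and 1668 lower, against 2477 without sham replicate 1, 2375 without sham replicate 2 and 2083 without day 3 replicate 1.

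Between the days, most cell cycle genes rose in endothelial cells. Mki67 rose from 0.517 ± 0.52 to 57.3 ± 1.70 CPM. Among genes that rose, Mxra8 (log2 fold change 3.02 ± 0.20, adjusted p = 7.91e-05) and Selp, P-selectin (2.77 ± 0.34, adjusted p = 8.28e-04) led, and among genes that fell, Gpc5 (-3.55 ± 0.81, adjusted p = 0.0138) and Apln, apelin (-3.24 ± 0.38, adjusted p = 6.86e-04) (edgeR, BH adjustment). Angiogenesis genes numbered 19, of which 5 rose, 6 fell and 8 did not pass (the same adjusted over the list alone, camera adjusted p = 0.449, not passing, direction up, median log2 fold change -0.14, mean 0.32). Examples were Lamb1 (3.39 ± 0.18) and Aplnr, the apelin receptor (5.71 ± 0.37). Of 25 cell cycle genes, 18 rose and 7 did not pass (21 rose adjusted over the list alone, camera adjusted p = 1.47e-42, adjusted p = 0.131 with an estimated correlation). Among them were Mki67 (6.67 ± 0.32) and Ccnb2 (5.86 ± 0.37). Of other-class markers measured here, 9 rose and 6 did not pass of 15 monocyte-macrophage markers and 4 fell and 10 did not pass of 14 astrocyte markers by edgeR. By edgeR, 1537 of 12689 genes were higher and 1185 lower, 2722 together, against 1713 without day 1 replicate 2, 1452 without day 3 replicate 1 and 1508 without day 3 replicate 2. Gpc5 did not pass without day 3 replicate 1 (log2 fold change -4.60) or day 3 replicate 2. A kept call had a log2 fold change of -2.15 (Gpc5, without day 1 replicate 2).

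In astrocytes, the supporting glia of the brain, every measured reactive astrocyte gene was higher on day 1 than in sham. Tm4sf1 rose from 7.18 ± 0.636 to 316 ± 8.83 CPM. Sham astrocytes lay mainly in cluster 6 (47.1%) and day 1 astrocytes in clusters 22 (34.8%) and 6 (31.6%). Markers that named the class make up 8 of the 16 homeostasis genes. The largest rises were those of Gdf15 (2852-fold, counting interval 789 to 23558, adjusted p = 1.98e-04) and Timp1, an inhibitor of matrix metalloproteinases (340.3-fold, counting interval 93.9 to 2815, adjusted p = 1.53e-04), and the largest falls those of Csmd3, a CUB and sushi domain protein (log2 fold change -1.74 ± 0.15, adjusted p = 6.13e-04) and Sfrp5, a secreted Wnt antagonist (-1.71 ± 0.47, adjusted p = 0.0439), by edgeR with BH adjustment. In the reactive astrocyte list, 20 rose of 20 measured genes (the same adjusted over the list alone, camera adjusted p = 2.76e-80). It included Tm4sf1, a tetraspanin-like membrane protein (5.46 ± 0.23) and S1pr3, a sphingosine 1-phosphate receptor (4.91 ± 0.22). Astrocyte homeostasis genes numbered 16, of which 4 fell and 12 did not pass (7 fell adjusted over the list alone, camera adjusted p = 1.09e-04, adjusted p = 0.631 with an estimated correlation). An example was Glul, glutamine synthetase (-0.67 ± 0.19). In the same cells, 6 rose and 11 did not pass of 17 monocyte-macrophage markers and 5 fell and 7 did not pass of 12 microglia markers by edgeR. edgeR called 2400 of 14228 genes on day 1 against sham, 1598 higher and 802 lower, against 347 without sham replicate 1, 331 without sham replicate 2, 1289 without day 1 replicate 2, 1055 with the same number of cells and 3738 with no filter on low counts. Sfrp5 and Glul did not pass without sham replicate 1, sham replicate 2 or day 1 replicate 2. Glul also did not pass with DESeq2 size factors (0.0544, edgeR, BH adjusted p).

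On day 3, nearly all reactive genes and every measured cell cycle gene were higher in astrocytes than in sham. Cdk1 rose from 0.823 ± 0.027 to 76.5 ± 0.0335 CPM. Day 3 cells lay mostly in clusters 6 (20.6%), 22 (20.2%), 21.7 (15.5%) and 21.8 (12.5%). Ranked by fold change, Vgf, a neuropeptide precursor (1870.1-fold, counting interval 334 to 74067, adjusted p = 7.38e-04) and Spp1 (log2 fold change 10.29 ± 0.69, adjusted p = 8.84e-05) rose most and Gdf10, a TGF-beta family member (-2.60 ± 0.20, adjusted p = 1.46e-04) and Ptgds, prostaglandin D synthase (-2.49 ± 0.48, adjusted p = 0.00693) fell most by edgeR with BH adjustment. Of 20 reactive astrocyte genes, 19 rose and 1 did not pass (20 rose adjusted over the list alone, camera adjusted p = 2.79e-59). Among them were Vim, vimentin (6.36 ± 0.23) and S100a10, an annexin-binding protein (4.47 ± 0.17). In the astrocyte homeostasis list, 9 fell and 7 did not pass of 16 measured genes (11 fell adjusted over the list alone, camera adjusted p = 2.25e-05, adjusted p = 0.432 with an estimated correlation). Cell cycle genes numbered 25, of which 25 rose (the same adjusted over the list alone, camera adjusted p = 1.78e-48). Examples were Rrm2, a ribonucleotide reductase subunit (5.10 ± 0.24) and Cdk1, the mitotic cyclin-dependent kinase (6.50 ± 0.35). For markers of other classes, 16 rose and 1 did not pass of 17 monocyte-macrophage markers and 7 fell and 5 did not pass of 12 microglia markers by edgeR. In all, 4504 of 14228 genes passed with edgeR, 2659 higher and 1845 lower, against 1644 without sham replicate 1, 1484 without sham replicate 2, 2967 without day 3 replicate 1 and 2733 with the same number of cells.

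From day 1 to day 3, nearly all cell cycle genes rose in astrocytes. Rrm2 rose from 3.22 ± 0.47 to 122 ± 18.0 CPM. Among genes that rose, Top2a (log2 fold change 5.37 ± 0.43, adjusted p = 6.34e-04) and Rrm2 (5.28 ± 0.24, adjusted p = 1.55e-04) led, and among genes that fell, Hspa1b (-3.83 ± 0.38, adjusted p = 0.00139) and Gdf15 (-2.94 ± 0.44, adjusted p = 0.00663) (edgeR, BH adjustment). Of 20 reactive astrocyte genes, 6 rose, 1 fell and 13 did not pass (6 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.243 with an estimated correlation). Among them were Vim (2.81 ± 0.20) and S100a10 (1.25 ± 0.14). In the cell cycle list, 24 rose and 1 did not pass of 25 measured genes (the same adjusted over the list alone, camera adjusted p = 2.17e-83, adjusted p = 0.0594 with an estimated correlation). It included Rrm2 (5.28 ± 0.24) and Cenpe, a kinetochore motor (5.14 ± 0.29). Of other-class markers measured here, 6 rose and 11 did not pass of 17 monocyte-macrophage markers by edgeR. By edgeR, 1101 of 14228 genes were higher and 478 lower, 1579 together, against 660 without sham replicate 1, 639 without sham replicate 2, 1027 without day 1 replicate 1, 988 without day 1 replicate 2, 830 without day 3 replicate 1, 690 with the stricter cell filter, 874 with the same number of cells and 2985 with no filter on low counts.

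In oligodendrocytes, the myelinating glia, every measured injury gene and most interferon response genes were higher on day 1 than in sham, and most myelin genes were lower. Serpina3n rose from 23.1 ± 1.07 to 953 ± 313 CPM. Sham cells lay in cluster 2 (98.2%) and day 1 cells in clusters 2 (48.2%) and 3 (35.2%). Markers that named the class make up 12 of the 16 myelin genes. The largest rises were those of Syt4, a synaptotagmin (log2 fold change 8.54 ± 0.77, adjusted p = 1.10e-04) and Klk9, a kallikrein-related peptidase (8.46 ± 0.24, adjusted p = 4.33e-07), and the largest falls those of Trpm3 (-1.69 ± 0.20, adjusted p = 4.36e-04) and Pigz, a mannosyltransferase of GPI anchor synthesis (-1.51 ± 0.18, adjusted p = 4.10e-04), by edgeR with BH adjustment. Injured oligodendrocyte genes numbered 18, of which 18 rose (the same adjusted over the list alone, camera adjusted p = 3.53e-30). Examples were Serpina3n, a serine protease inhibitor (5.37 ± 0.23) and Cd63 (2.63 ± 0.15). Of 20 interferon response genes, 16 rose and 4 did not pass (the same adjusted over the list alone, camera adjusted p = 6.49e-08, adjusted p = 0.231 with an estimated correlation). Among them were Ifit1, an interferon-induced protein (4.64 ± 0.36) and Rsad2 (5.02 ± 0.44). In the myelin list, 1 rose, 10 fell and 5 did not pass of 16 measured genes (the same adjusted over the list alone, camera adjusted p = 2.45e-06, adjusted p = 0.258 with an estimated correlation). In the same cells, 8 rose and 7 did not pass of 15 monocyte-macrophage markers and 6 fell and 8 did not pass of 14 endothelial markers by edgeR. edgeR called 4033 of 13231 genes on day 1 against sham, 2108 higher and 1925 lower, against 1731 without sham replicate 1 and 1927 without sham replicate 2.

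On day 3, most injury and antigen presentation genes were higher in oligodendrocytes than in sham. H2-D1 rose from 55.8 ± 1.39 to 269 ± 12.6 CPM. Day 3 cells lay in clusters 3 (51.3%) and 2 (29.7%). Ranked by fold change, Spp1 (2288-fold, counting interval 633 to 18898, adjusted p = 4.47e-07) and Klk8, a kallikrein-related peptidase (log2 fold change 8.65 ± 0.39, adjusted p = 3.99e-06) rose most and Ptgds (-3.12 ± 0.27, adjusted p = 6.78e-05) and Lsamp (-2.85 ± 0.31, adjusted p = 2.11e-04) fell most by edgeR with BH adjustment. Injured oligodendrocyte genes numbered 18, of which 15 rose and 3 did not pass (16 rose adjusted over the list alone, camera adjusted p = 7.55e-30). Examples were Serpina3n (6.07 ± 0.24) and H2-D1, an MHC class I heavy chain (2.27 ± 0.10). Of 15 antigen presentation genes, 10 rose and 5 did not pass (11 rose adjusted over the list alone, camera adjusted p = 2.06e-11). Among them were H2-D1 (2.27 ± 0.10) and B2m, the light chain of MHC class I (2.71 ± 0.14). In the myelin list, 3 rose, 9 fell and 4 did not pass of 16 measured genes (the same adjusted over the list alone, camera adjusted p = 0.0280, adjusted p = 0.560 with an estimated correlation). It included Trf, transferrin (1.78 ± 0.22) and Gjc3, a connexin (-0.82 ± 0.14). For markers of other classes, 15 rose of 15 monocyte-macrophage markers and 1 rose, 10 fell and 3 did not pass of 14 astrocyte markers by edgeR. In all, 4789 of 13231 genes passed with edgeR, 2508 higher and 2281 lower, against 2452 without sham replicate 1, 2414 without sham replicate 2 and 2770 without day 3 replicate 2.

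Between day 1 and day 3, several antigen presentation genes and most cell cycle genes rose in oligodendrocytes. Hspa1b fell from 400.0 ± 415 to 36.9 ± 0.742 CPM. Among the largest rises was that of Spp1 (log2 fold change 2.76 ± 0.16, adjusted p = 1.63e-04), and among the largest falls were those of Hspa1b (-3.44 ± 0.73, adjusted p = 0.0208) and Hspa1a, an inducible HSP70 (-3.27 ± 0.78, adjusted p = 0.0291), by edgeR with BH adjustment. Antigen presentation genes numbered 15, of which 5 rose and 10 did not pass (10 rose adjusted over the list alone, camera adjusted p = 3.16e-11, adjusted p = 0.120 with an estimated correlation). Examples were H2-D1 (1.75 ± 0.10) and B2m (1.80 ± 0.13). Of 25 cell cycle genes, 18 rose and 7 did not pass (22 rose adjusted over the list alone, camera adjusted p = 7.77e-19, adjusted p = 0.333 with an estimated correlation). Among them were Birc5 (4.58 ± 0.51) and Tpx2, a spindle assembly factor (1.93 ± 0.24). The class included cycling sub-cluster 35.6 (led by Top2a and Rrm2), and the list was not tested without it. Of other-class markers measured here, 10 rose and 5 did not pass of 15 monocyte-macrophage markers and 6 fell and 8 did not pass of 14 astrocyte markers by edgeR. By edgeR, 892 of 13231 genes were higher and 687 lower, 1579 together, against 802 without sham replicate 1, 767 without sham replicate 2, 864 without day 3 replicate 1 and 216 without day 3 replicate 2. Hspa1b did not pass when either day 3 replicate was left out, nor did Hspa1a, which also did not pass without sham replicate 2. Kept calls had log2 fold changes of -1.53 (Hspa1b, without day 1 replicate 1) and -1.05 (Hspa1a, without day 1 replicate 1).

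**Figure D3:**
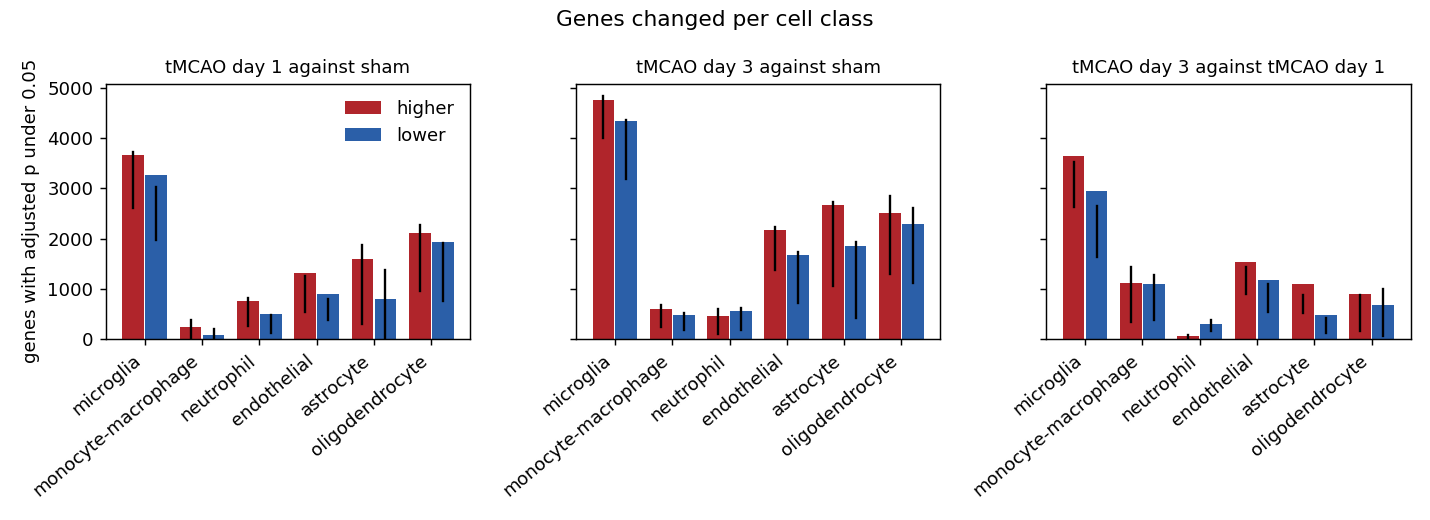
Number of genes higher (red) and lower (blue) with adjusted p under 0.05 in 6 classes and 3 contrasts, by edgeR. Black lines span the counts when each library was left out in turn.

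**Figure D4:**
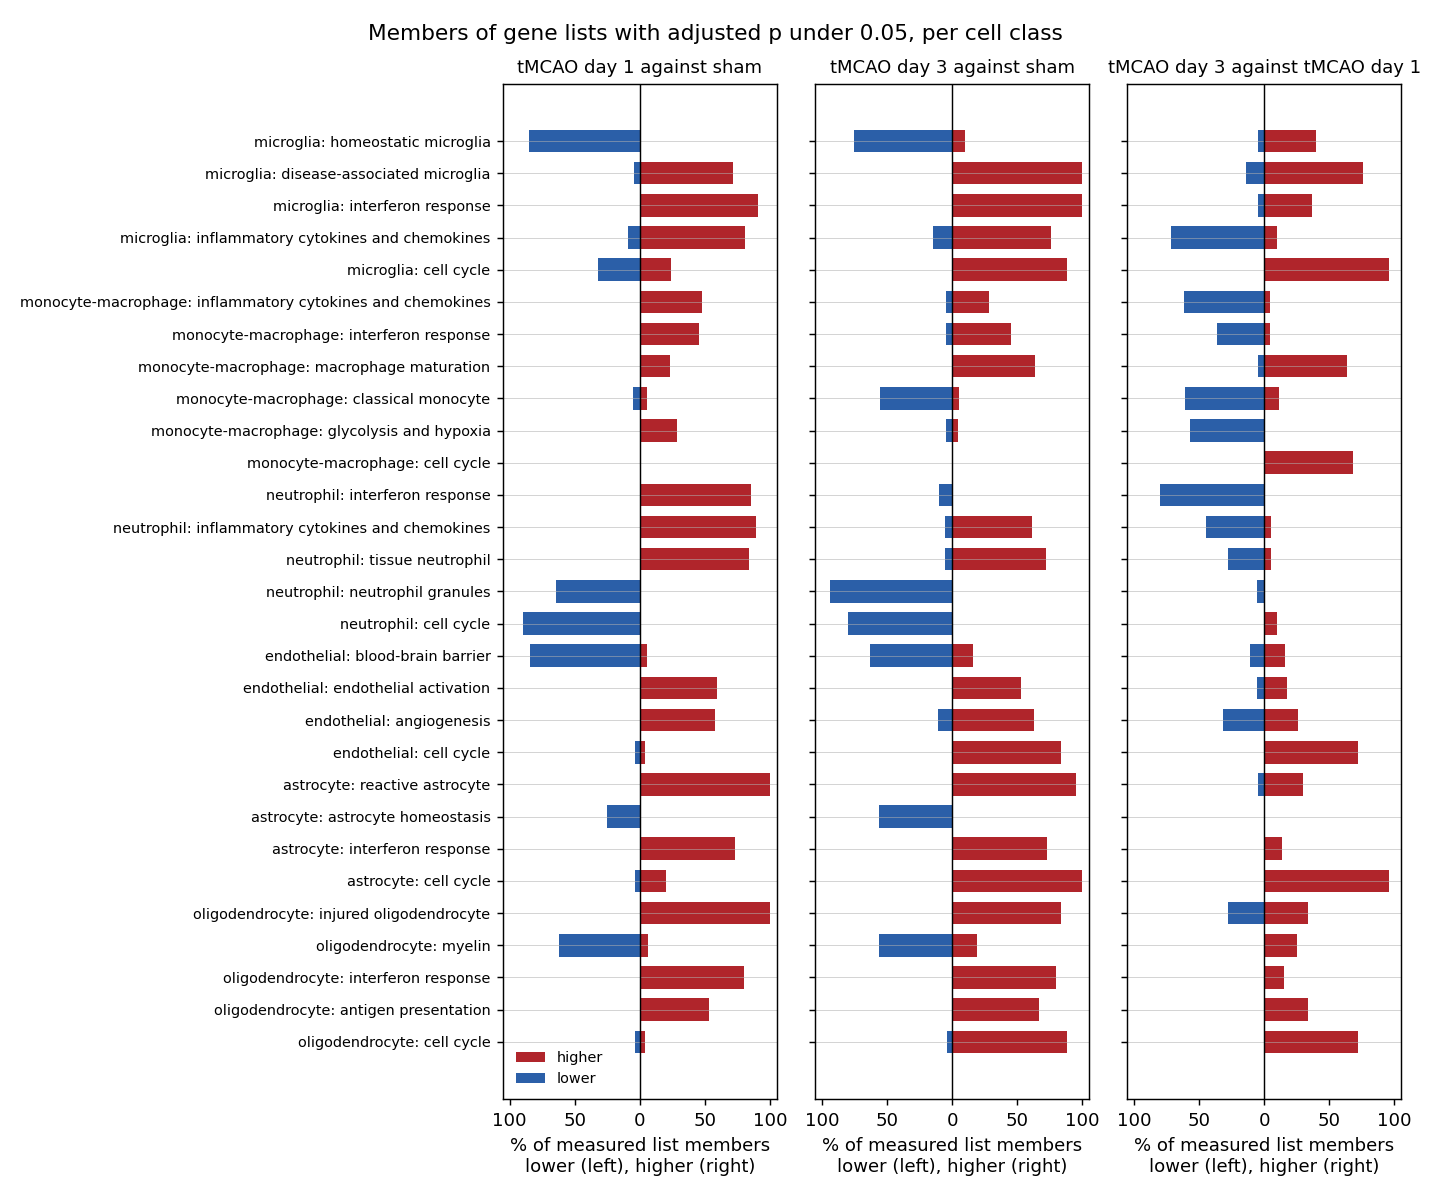
Percent of measured members of each list that were higher (right) or lower (left) with adjusted p under 0.05, by class and contrast. Bars of the cell cycle list point right on day 3 in microglia, endothelial cells, astrocytes and oligodendrocytes.

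Of lists of other classes' markers, camera called higher and lower 1 and 5, 2 and 5 and 2 and 1 of 17 in microglia, 0 and 2, 1 and 4 and 2 and 3 of 7 in monocyte-macrophages, 0 and 3, 0 and 3 and 0 and 1 of 5 in neutrophils, 1 and 2, 3 and 3 and 3 and 1 of 13 in endothelial cells, 2 and 2, 3 and 3 and 4 and 0 of 16 in astrocytes and 2 and 1, 4 and 3 and 3 and 1 of 12 in oligodendrocytes (day 1 and day 3 against sham, day 3 against day 1), of which 1 held with an estimated correlation. Across all classes and contrasts, 183 list tests were made, of which 90 passed upward and 35 downward by camera with its preset correlation of 0.01. With a correlation estimated from these libraries, 17 of those calls held: in microglia those of the homeostatic microglia (day 1 and day 3), disease-associated microglia (day 1 and day 3), inflammatory cytokine and chemokine (day 1 and day 3) and cholesterol and lipid handling (day 1 and day 3) lists, in endothelial cells those of the inflammatory cytokine and chemokine (day 1) and angiogenesis (day 1) lists, in astrocytes those of the inflammatory cytokine and chemokine (day 1), reactive astrocyte (day 1 and day 3) and cell cycle (day 3) lists, in oligodendrocytes those of the injured oligodendrocyte (day 1 and day 3) and antigen presentation (day 3) lists, all against sham. Of 799 calls of genes taken by the fixed rule, 590 kept their call whichever library was left out and 209 lost it in at least 1 such fit, with 0 changes of sign, while the fitted fold change of 202 moved by over 1.5 times.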

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

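The comparisons of the days and of the unnamed sub-clusters were chosen after the data were seen. In microglia, 375 genes changed in opposite directions on the 2 days, each passing against sham on both days and between the days by edgeR, with 246 lower on day 1 and higher on day 3 and 129 the other way round. Such genes numbered 63 in endothelial cells, 27 in oligodendrocytes, 9 in astrocytes, 3 in monocyte-macrophages and 1 in neutrophils.

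Most sub-clusters left outside the named classes held sham cells, and those given here, chosen after their counts were seen, held none in either sham library. On day 1, sub-cluster 17.5, led by Mmp12, Lpl and Ccl9, made up 1.36% of cells on average, sub-cluster 29.3, led by Gjb1, Il33 and Klk9, 0.943%, and sub-cluster 11.7, led by Il11, Il6 and Stc1, 0.34%. On day 3, sub-cluster 29.5, with Syt4 and Pou3f1 among its leading genes, made up 1.91%, sub-cluster 29.7, led by Hexim1, Dusp10 and Tob1, 1.83%, and sub-cluster 11.8, led by Mgp and Rgs5, 0.363%. These genes define the sub-clusters, and the shares were not tested between groups.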

How the results depend on the processing

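Every alternative named here was planned except the fits without cycling clusters and without myeloid-abundant genes, and the cause of each change was not tested. Days are set against sham unless day 1 is named. With each library left out in turn, 1 of 18 counts of called genes stayed within 1.5 times its value. The counts then ran (in parentheses with all libraries), in microglia 4595 to 6732 (day 1, 6930) and 4270 to 6098 (day 3 against day 1, 6593). They were, in monocyte-macrophages 32 to 578 (day 1, 314), 423 to 1209 (day 3, 1085) and 727 to 2708 (day 3 against day 1, 2212). They were, in neutrophils 375 to 1306 (day 1, 1266), 267 to 1208 (day 3, 1019) and 185 to 462 (day 3 against day 1, 353). They were, in endothelial cells 915 to 2049 (day 1, 2208), 2083 to 3968 (day 3, 3833) and 1452 to 2529 (day 3 against day 1, 2722). They were, in astrocytes 331 to 3158 (day 1, 2400), 1484 to 4646 (day 3, 4504) and 639 to 1286 (day 3 against day 1, 1579). They were, in oligodendrocytes 1731 to 4182 (day 1, 4033), 2414 to 5462 (day 3, 4789) and 216 to 1872 (day 3 against day 1, 1579). With other settings, the same number of cells gave 612 (day 3) and 207 (day 3 against day 1) for monocyte-macrophages. It gave 513, 312 and 49 for neutrophils and 1055, 2733 and 874 for astrocytes (day 1, day 3, day 3 against day 1), and 1441 for endothelial cells on day 1. Leiden resolution 2 gave 1258, 1739 and 1141 for monocyte-macrophages in that order. For them, no filter on low counts gave 0 (edgeR, 1977 at an unadjusted p under 0.05), 281 and 1089 in that order. For astrocytes it gave 3738 on day 1 and 2985 on day 3 against day 1. The DESeq2 Wald test gave 711 for monocyte-macrophages on day 1, and the stricter cell filter 690 for astrocytes on day 3 against day 1. DESeq2 size factors, doublets kept and other classes' markers left out moved none of 18 counts of called genes by over 1.5 times, cycling clusters left out none of the 9 of microglia, monocyte-macrophages and oligodendrocytes, and myeloid-abundant genes left out none of the 9 of endothelial cells, astrocytes and oligodendrocytes. The share of higher among called genes was 56.4% with the same number of cells and 56.5% at Leiden resolution 2, against 75.5%, for monocyte-macrophages on day 1, and 51.9% with no filter, against 69.7%, for astrocytes on day 3 against day 1.

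Of 12 share tests, 4 kept their direction and side of the threshold whichever library was left out. Log2 fold changes of shares then ran from 2.60 to 5.32 (monocyte-macrophages, day 1), 2.12 to 4.83 (monocyte-macrophages, day 3 against day 1), 2.12 to 4.03 (neutrophils, day 3), -0.86 to 2.02 (neutrophils, day 3 against day 1), -0.96 to -0.89 (microglia, day 3), -0.94 to -0.86 (microglia, day 3 against day 1), 1.49 to 2.27 (T/NK cells, day 3) and 0.74 to 1.72 (T/NK cells, day 3 against day 1). By edgeR with Benjamini-Hochberg adjustment, TMM factors gave -0.014 (adjusted p = 0.941) for microglia on day 3, 0.032 (adjusted p = 0.869) for microglia on day 3 against day 1, 2.10 (adjusted p = 0.0244) for T/NK cells and 3.82 (adjusted p = 0.0342) for monocyte-macrophages. The stricter cell filter gave 3.05 (adjusted p = 0.0669) for neutrophils on day 3, and Leiden resolution 2 -0.429 (adjusted p = 0.211) for microglia on day 3 against day 1. Keeping doublets changed no share call.

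Of 237 gene results, 191 kept their call in every such fit, and with DESeq2 size factors 1 lost it. Changes of sign concerned tdTomato in contrasts that did not pass, where its log2 fold change with a library left out ran, in microglia on day 3 -0.093 to 0.209, in monocyte-macrophages on day 1 -0.131 to 0.208 (-0.029 with DESeq2 size factors), in monocyte-macrophages on day 3 -0.279 to 0.185 (-0.056 with DESeq2 size factors), in monocyte-macrophages on day 3 against day 1 -0.272 to 0.189, in neutrophils on day 1 -0.175 to 0.553, in neutrophils on day 3 -0.601 to 0.124, in oligodendrocytes on day 3 against day 1 -0.363 to 0.130. Of the list calls, 17 held with an estimated correlation, 57 were lost with fry and 4 with the replicate block. The endothelial activation list in endothelial cells on day 3 against day 1 did not pass (adjusted p = 0.994) and turned direction with fry (adjusted p = 0.948) and with the block (adjusted p = 0.974).

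The labels number the replicates of each group alike, but give no pairing, and 2 numbers cannot show one. Correlations of same-numbered deviations across genes ran by class from 0.06 to 0.46 for sham with day 1, over 0.1 in 3 of 6 classes, and from -0.25 to 0.07 for pairs with day 3, so the numbers were not treated as pairs. With the replicate number as a block, counts of called genes moved by over 1.5 times to 474 for monocyte-macrophages on day 1 and 1021 for oligodendrocytes on day 3 against day 1. The microglia share on day 3 against day 1 then had a log2 fold change of -0.901 (adjusted p = 0.0613) by edgeR with BH adjustment, and 4 of 237 gene results did not pass.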

Other observations

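The tests of the day 1 libraries, of tdTomato and of doublets by class were chosen after the result, or the levels behind it, were seen. Classes whose shares are left out of the report also changed them on day 3 against sham by edgeR with BH adjustment. Dendritic cells rose from 0.0776% ± 0.0716 to 4.43% ± 1.42 of cells (log2 fold change 5.81 ± 0.85, adjusted p = 0.00673). Astrocytes fell from 17.9% ± 0.0227 to 3.46% ± 0.572 (-2.38 ± 0.39, adjusted p = 0.00673), pericytes from 4.08% ± 0.335 to 1.19% ± 0.032 (-1.77 ± 0.30, adjusted p = 0.00673) and neural progenitors or neuroblasts from 1.86% ± 0.235 to 0.348% ± 0.089 (-2.41 ± 0.28, adjusted p = 0.00673). These calls held in every alternative that was run, but with TMM factors over the class counts the log2 fold changes became 6.73 (adjusted p = 0.00832) for dendritic cells, -1.47 (adjusted p = 0.0237) for astrocytes, -0.86 (adjusted p = 0.0476) for pericytes and -1.49 (adjusted p = 0.0114) for neural progenitors or neuroblasts. Of the other classes that passed on day 3, monocyte-macrophages apart, each lost its call in at least 1 alternative.

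Other lists were tested in the same fits. Among cholesterol and lipid handling genes, 14 rose, 2 fell and 6 did not pass of 22 (the same adjusted over the list alone, camera adjusted p = 6.10e-07) in microglia on day 3 against sham. Of oxidative stress and metallothionein genes, 14 rose and 3 did not pass of 17 (the same adjusted over the list alone, camera adjusted p = 2.78e-11, adjusted p = 0.162 with an estimated correlation) in microglia on day 1. Of genes of dissociation and early response, 20 fell and 3 did not pass of 23 (1 rose and 21 fell adjusted over the list alone, camera adjusted p = 1.30e-11, adjusted p = 0.0894 with an estimated correlation) in microglia on day 3.

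Monocyte-macrophage markers rose in endothelial cells, astrocytes and oligodendrocytes on day 3, for which free RNA from myeloid cells and undetected doublets are candidate explanations. As the whole cause, doublets would put at least 50% of the marker UMIs into the 5% of cells with the most, and at most 30% would argue against it. These cells held at most 28.5% per library in oligodendrocytes, which argues against doublets as the whole cause there. They held 35.5% and 36.5% in astrocytes, between these bounds. In endothelial cells (at most 22.9%) the test cannot decide, since 94.1% and 89.9% held a marker UMI in sham. Doublets stay open in both classes. Free RNA would give the 3 classes alike marker levels, relative to the myeloid level, and the highest class exceeded the lowest 2.01-fold in one day 3 library and 1.34-fold in the other (bound 2), so free RNA and expression in these cells cannot be told apart. Spp1 reached 0.78 and 1.15 times the relative level of the median marker in endothelial cells and 1.39 and 1.54 times in oligodendrocytes, as free RNA would give, and in astrocytes 1.28 and 2.12 times, which leaves the source open.

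tdTomato UMIs outside the labelled myeloid classes may come from free RNA of labelled cells, in which case tdTomato would reach at most 2 times the relative level of the median myeloid marker. It reached 294 and 323 times in endothelial cells of the sham libraries, and 23.4 and 27.8 times on day 3, and at least 6.59 times the 90th percentile of the markers, which argues against free RNA as the whole source there. In astrocytes of day 3 it reached 5.76 and 11.3 times and in oligodendrocytes 5.06 and 5.35 times the median marker, but in no library over 2.72 times that percentile, so free RNA stays open there. In all 3 classes 1 or 2 markers lay above tdTomato, and the limit of 3 times that percentile was set after these values were seen, in place of a looser one that had placed astrocytes with endothelial cells. Recombination in some cells, leak of the reporter, mapping, doublets and the stroke itself stay open and untested for tdTomato.

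The day 1 libraries differed in their share of monocyte-macrophages (9.06% and 1.38%) and of neutrophils (6.24% and 1.19%). A sham library labelled day 1 would have sham-like microglia, but the median inflammatory or interferon gene in microglia lay 1.78 above the sham mean (log2) in day 1 replicate 2 and 1.87 above it in day 1 replicate 1. A loss of leukocytes during preparation would lower every leukocyte class alike, but the folds between the libraries ran from 1.82 in dendritic cells to 6.56 in monocyte-macrophages, a ratio of 3.59, which argues against an even loss as the whole cause. A different extent of injury, or of the tissue taken, stays open and was not tested.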
